A study of Macaca fascicularis and Macaca mulatta with 29 samples.

How the data were processed

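The series holds 29 samples, of which 23 had processed files here: 10 RNA libraries and 13 methylation libraries. The 6 CUT&RUN samples of a histone mark were not analysed here. Per the labels' protocols, RNA of single 16-cell embryos was amplified with SMART-Seq v4 and placenta RNA was selected with oligo-dT beads and primed with random hexamers. Embryo and adult tissue methylation libraries were made by post-bisulfite adaptor tagging, from lysed embryos or extracted DNA. The cynomolgus placenta, both rhesus placentas and both fibroblast libraries were made by ligating methylated adaptors before bisulfite conversion. Lambda DNA was added to all methylation libraries, and its conversion rate was not used here. Groups and replicate numbers were taken from the sample titles.

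The deposited RNA files give FPKM per gene symbol, made by the authors with Cufflinks. The submitters' processing notes name Trim Galore, TopHat2 2.1.1, Cufflinks 2.2.1, Bismark 0.20.0, Picard and Bowtie2 2.3.4.1, and the build rheMac8. The build of the cynomolgus files and the annotation are not given in the sources used here. Which tool made which file is read from what each is used for. FPKM divides reads by gene length and library size, so a group of very high genes lowers all others, and the 10 highest genes held 11.58 to 12.81% of FPKM in androgenetic and 7.084 to 8.93% in parthenogenetic libraries. FPKM totals ran from 508822 to 538466 in the embryos and were 342690 and 298378 in the wild-type and SCNT placenta, whose relative depth was 0.818 for SCNT over wild type. The deposited methylation files give the methylated fraction of each CpG to 2 decimals, per the file contents, without coverage. A fraction from few reads therefore counts as much as one from many, and no interval or read test was possible.

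FPKM was transformed as log2(FPKM + 1), and 1 duplicated symbol in the embryo files and 7 in the placenta files were left out. Genes with at least 1 FPKM in at least 4 of the 8 embryo libraries were fitted with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3, without covariates, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. An exact 0 was described as listed at 0. Of 16093 symbols 15017 matched the T2T-MFA8v1.1 annotation, which was used for chromosome names and not for coordinates. The 38 gene lists were written before the data were examined, from general knowledge of human and mouse genes, and the 23 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry. On simulated libraries with 200 genes changed, the test recovered 0% of changes of 1 and 81% of changes of 2 on the log2 scale, with 6 unchanged genes of the 6614 called in the latter. The adjusted threshold loosens as more genes change. The data gave 2317 calls, among them RPS6 at a log2 difference of 0.837, so these shares do not carry over to the data. With 16 members of the oocyte transcript list shifted by 1, camera called 2 lists, that one and the DNA methylation list, which shared 1 of its 12 tested members (DPPA3) with it.

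The placenta libraries, 1 per group, were compared by size. A gene was called at a difference of at least 1 in log2(FPKM + 1) with at least 5 FPKM in the higher library, and a list by the percentile of its median among 10000 random lists matched on mean expression. On simulated data 6% of 100 unshifted lists fell beyond the central 95% of their random lists, and a list of 20 members shifted by 1 reached percentile 100. The simulated data were the measured differences shuffled between genes, with lists drawn at random, so this checks the calculation only. Members of a real list can vary together, which random lists do not reproduce, so a percentile is not a p-value.

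CpG levels were averaged in non-overlapping tiles of 1 kb with at least 5 CpGs in every library compared, on chromosomes 1 to 20 and X, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The size rules were 50 percentage points between androgenetic and parthenogenetic embryos, 40 points for a tile lower in 1 tissue than in every other library, and 30 points between the rhesus placentas. Intermediate means 35 to 65%, and dense means at least 20 CpGs per kb. Called tiles no more than 1 kb apart were joined into regions. Positions count from 1. With alternate CpGs of the parthenogenetic library, odd against even, 97.5% of 200 tiles shifted by 60 points were recovered and 42 unshifted tiles of 551487 were called. These tiles held at least 5 CpGs in each set, more than a called tile needs.

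Before the data were examined, a rule fixed the names. It took the 12 largest rises and 12 largest falls with a mean of at least 5 FPKM in the higher group and no overlap between groups, every imprinted gene past the threshold, up to 4 members of each other list, and the 10 regions per class and direction with the most CpGs. The text gives a part of these and says where a name was chosen after its values were seen. Alternatives fixed at the same time covered the pseudocount, filters, scalings, the replicate number as a block, each library left out, tile size, CpG minimum and size limits. Fits on autosomal genes only, the comparisons on CpGs measured in both libraries and the list of autosomal falls were added after seeing the data.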

Results

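Cynomolgus macaque (Macaca fascicularis) embryos with genomes from only 1 parent were profiled at the 16-cell stage. Androgenetic embryos carry only paternal genomes and parthenogenetic embryos carry only maternal genomes, so that genes and regions set apart by parent of origin can be read from the difference between them. RNA was measured in 4 androgenetic and 4 parthenogenetic embryos, with 1 embryo per library, and DNA methylation in 1 library of each kind. Methylation was also measured in cortex, cerebellum, heart, liver, kidney, small intestine and placenta of cynomolgus macaques, with 1 library per tissue. In rhesus macaques (Macaca mulatta), 1 wild-type placenta and 1 placenta from somatic cell nuclear transfer (SCNT, the cloning method in which a somatic nucleus is placed in an enucleated oocyte) were profiled for methylation and RNA, and 2 libraries of donor fibroblasts for methylation. The series title names imprinting defects in cloned placenta as its subject.

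The RNA values were FPKM per gene symbol and gave no read counts. Each 16-cell library listed 16093 symbols, of which 5990 to 6068 reached 1 FPKM in androgenetic embryos and 6619 to 6911 in parthenogenetic embryos. The smallest steps between low FPKM values placed the depth of the libraries between 0.742 and 1 times that of androgenetic library 1. Pearson correlations across genes were 0.932 to 0.95 between androgenetic libraries, 0.916 to 0.956 between parthenogenetic libraries and 0.78 to 0.83 between the groups. The methylation values were fractions per CpG without coverage, so the depth behind each level is unknown. The libraries measured from 14871462 CpGs in androgenetic embryos to 27286577 in the wild-type rhesus placenta.

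RNA from the X chromosome was close to 0 in androgenetic embryos. X-linked genes summed to 162.8 to 434.1 FPKM in the 4 androgenetic embryos and to 16601 to 17989 FPKM in the 4 parthenogenetic embryos. Of 200 X-linked genes tested, 188 fell in androgenetic embryos, with a median log2 difference of -3.57, against -0.638 to -0.142 in 1000 sets of autosomal genes matched on parthenogenetic level. All 12 genes with the largest falls were X-linked. COX7B, a subunit of cytochrome c oxidase, stood at 1.18 ± 0.904 FPKM in androgenetic and 1426 ± 349 FPKM in parthenogenetic embryos (SD, n = 4 each), a log2 difference of -9.42 ± 0.349 (SE; limma adjusted p = 1.09e-09). NDUFA1, a subunit of respiratory complex I, stood at 0.111 ± 0.154 and 651 ± 44.0 FPKM, and the translation initiation factor gene EIF1AX at 1.73 ± 0.774 and 992 ± 214 FPKM. PQBP1, FUNDC1, SSR4, TCEAL8, PRAF2, MCTS1, UXT, BCAP31 and PBDC1 completed the 12, with parthenogenetic means of 300 to 655 FPKM and androgenetic means of 0.0785 to 1.79 FPKM. The glycolytic enzyme gene PGK1 and the purine salvage gene HPRT1 behaved alike, at 0.168 ± 0.135 against 138 ± 23.8 FPKM and at 11.1 ± 9.52 against 484 ± 122 FPKM. Only 2 X-linked genes were higher in androgenetic embryos. These were ACE2, at 15.6 ± 6.80 against 3.92 ± 3.66 FPKM (adjusted p = 0.00843), and the oocyte growth factor gene BMP15, at 8.85 ± 4.72 against 3.29 ± 1.64 FPKM (adjusted p = 0.0496). Both were picked out after their values were seen, and for both the libraries of the groups overlapped. A gene's chromosome was taken by symbol from the T2T-MFA8v1.1 annotation.

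**Figure D1:**
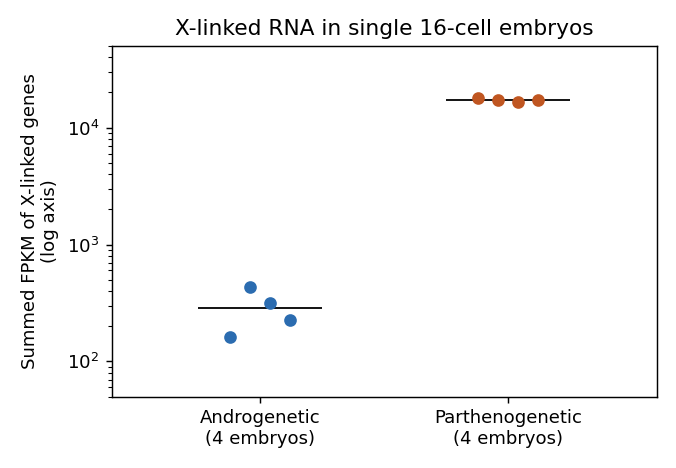
Summed FPKM of X-linked genes in each 16-cell embryo, on a log axis; each point is 1 library and each line the mean of 4. The androgenetic embryos lie between 162.8 and 434.1 FPKM and the parthenogenetic embryos between 16601 and 17989 FPKM.

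Across all chromosomes, 2317 of 6614 tested genes differed between the embryos, 660 higher and 1657 lower in androgenetic embryos (limma on log2(FPKM + 1), adjusted p under 0.05). On autosomes 610 genes were higher and 1379 lower of 6038 tested. The libraries of the groups did not overlap for 2145 genes, 32.4% of those tested, where chance gives 2.86%. The median log2 difference of all tested genes was -0.346, and the split between directions moved with the scaling. Median-ratio scaling brought the median to -0.07 and gave 992 genes higher and 1173 lower, 45.8% higher against 28.5% without it. Quantile normalization brought it to 0.04 and gave 1103 higher and 1011 lower, 52.2% higher. Differences on the log2(FPKM + 1) scale understate the change of genes with low values. The sources used here do not say whether the embryos came from separate animals, so the p-values measure the spread between these embryos. Within a group, single embryos also differed by chromosome, with 7 of 160 autosome medians beyond all 2000 random gene sets. The largest were chromosome 19 in parthenogenetic embryo 1 (-0.348 on the log2 scale) and chromosome 10 in parthenogenetic embryo 4 (0.31). The cause was not tested.

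Genes of embryonic genome activation, the first burst of transcription from the embryo's own genome, were higher in androgenetic embryos. Of 16 tested members of this list, 12 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.78e-05; adjusted p = 0.291 with an estimated correlation). ZSCAN4, a zinc-finger gene expressed around genome activation, had the largest rise of any gene that met the naming rule, from 55.7 ± 64.8 FPKM in parthenogenetic to 1590 ± 200 FPKM in androgenetic embryos (log2 difference 6.98 ± 1.26, SE; adjusted p = 0.00103). Its parthenogenetic libraries stood at 0.982, 0, 125 and 96.2 FPKM, so the size of this difference leans on the libraries near 0. The homeobox gene DUXB stood at 576 ± 182 against 64.6 ± 32.1 FPKM (log2 difference 3.23 ± 0.364; adjusted p = 2.67e-05), and the cyclin gene CCNA1 at 74.0 ± 32.4 against 4.77 ± 3.71 FPKM (3.75 ± 0.477; adjusted p = 7.2e-05). LEUTX and DUXA, homeobox genes of the same list named after their values were seen, stood at 170 ± 184 against 7.03 ± 4.25 FPKM and at 2832 ± 1081 against 705 ± 319 FPKM. The members that fell were EIF1AX, which is X-linked, and the homeobox gene DPRX, at 79.6 ± 40.4 against 681 ± 90.9 FPKM (-3.22 ± 0.334; adjusted p = 1.28e-05). Median-ratio scaling called 12 members higher and 2 lower, and quantile normalization 13 and 2. ZSCAN4, the DUX genes and the NLRP genes named further on have close copies in primate genomes, among which the authors' quantification could divide reads.

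Other large rises were found in CPHXL, a homeobox gene (303 ± 79.3 against 3.44 ± 5.62 FPKM), the RNA-binding regulator LIN28B (39.95 ± 16.7 against 0.369 ± 0.268 FPKM; adjusted p = 8.35e-07), the primase-polymerase gene PRIMPOL (128 ± 21.7 against 5.84 ± 5.60 FPKM) and NANOGNB (155 ± 95.7 against 4.72 ± 2.07 FPKM). ZNF735, PPP1R14A, C4H6orf163 and ZNF442 rose by 4.65 to 6.09 on the log2 scale. DYNLRB2 and FAM218A were listed at 0 in all 4 parthenogenetic libraries and averaged 27.3 and 22.0 FPKM in androgenetic embryos. Because the 12 largest falls were X-linked, autosomal falls were chosen in addition after the values were seen. These included SMIM1 (0.521 ± 0.530 against 71.1 ± 15.05 FPKM), TMEM242 (5.53 ± 1.43 against 104 ± 8.42 FPKM) and the interferon-induced membrane protein gene IFITM1 (44.0 ± 35.9 against 603 ± 291 FPKM).

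Among genes known as imprinted in human or mouse, the direction followed the expressed parental allele for some and went against it for others. SNRPN, a paternally expressed gene that encodes a splicing protein, stood at 61.1 ± 19.3 FPKM in androgenetic and 1.18 ± 1.16 FPKM in parthenogenetic embryos (log2 difference 4.91 ± 0.400, SE; adjusted p = 1.31e-06). All 5 tested paternally expressed genes passed the test, 3 higher and 2 lower in androgenetic embryos. INPP5F and ZNF331 were higher at low levels (3.26 ± 1.52 against 0.759 ± 0.444 FPKM and 4.07 ± 2.95 against 0.954 ± 0.303 FPKM), while MEST (6.46 ± 2.71 against 18.8 ± 5.98 FPKM) and NDN (0.0935 ± 0.187 against 1.54 ± 0.407 FPKM) were lower. Of 11 tested maternally expressed genes, 3 were lower and 2 higher in androgenetic embryos. GNAS, which encodes a G-protein subunit, stood at 3.37 ± 1.09 against 30.7 ± 12.3 FPKM (-2.82 ± 0.378; adjusted p = 0.000111), NLRP2 at 6.81 ± 5.31 against 101 ± 33.6 FPKM (adjusted p = 4.39e-05) and UBE3A at 4.05 ± 2.35 against 10.2 ± 2.52 FPKM. SLC22A2 (5.65 ± 3.91 against 0.743 ± 0.734 FPKM) and ZNF597 (17.7 ± 7.40 against 7.34 ± 1.68 FPKM) were the higher ones. Counts adjusted over the list alone were the same for both lists, and neither list as a whole passed camera (adjusted p = 0.199 and 0.974). Several of these calls ended when 1 library was left out. UBE3A was no longer called without androgenetic embryo 2 or 3 or without parthenogenetic embryo 1, 2 or 3 (adjusted p = 0.0701, 0.0877, 0.0512, 0.0833 and 0.0608; up to 0.162 over all alternatives), and ZNF597 without androgenetic embryo 1 or 3 or parthenogenetic embryo 1 or 2 (0.09, 0.0616, 0.0636 and 0.0573; up to 0.09). INPP5F ended without androgenetic embryo 4 or parthenogenetic embryo 2 (0.0547 and 0.0576; up to 0.0672) and ZNF331 without androgenetic embryo 3 or parthenogenetic embryo 4 (0.0614 and 0.065; up to 0.08). MEST was no longer called after quantile normalization (adjusted p = 0.0756). Of the maternally expressed genes, median-ratio scaling and quantile normalization each called 2 higher and 2 lower.

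**Figure D2:**
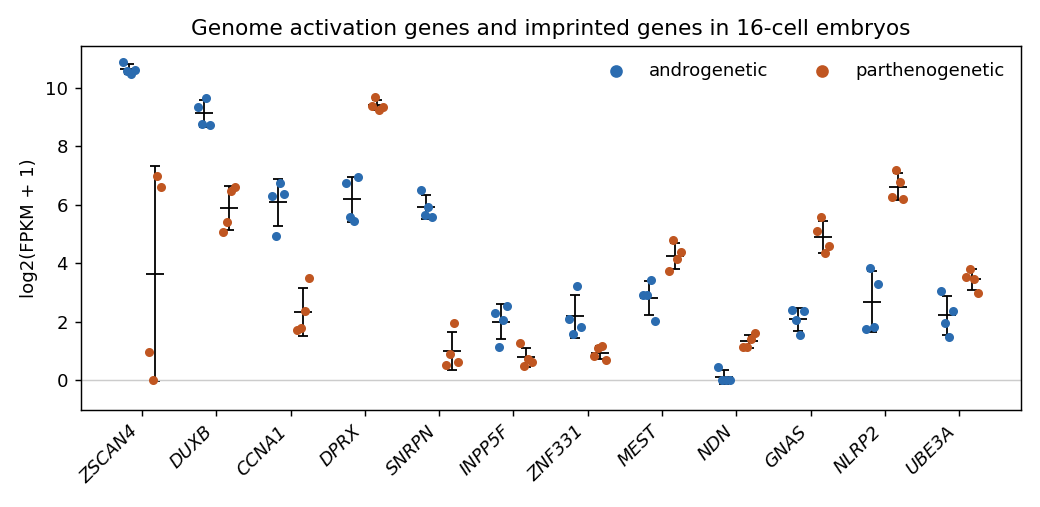
FPKM of genome activation genes (ZSCAN4 to DPRX), paternally expressed imprinted genes (SNRPN to NDN) and maternally expressed imprinted genes (GNAS to UBE3A) as log2(FPKM + 1); points are single embryos, and crosses the mean and SD of 4. SNRPN averaged 61.1 FPKM in androgenetic and 1.18 FPKM in parthenogenetic embryos, and NLRP2 6.81 and 101 FPKM.

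Nuclear genes of oxidative phosphorylation were lower in androgenetic embryos. Of 17 tested members 10 fell and 7 did not pass the test, or 11 fell adjusted over the list alone (camera adjusted p = 0.00974; adjusted p = 0.291 with an estimated correlation). Besides X-linked NDUFA1, the complex I gene NDUFB5 stood at 107 ± 23.5 against 466 ± 117 FPKM (adjusted p = 4.96e-05), the complex III gene UQCRB at 253 ± 53.9 against 763 ± 227 FPKM (adjusted p = 0.000569) and the succinate dehydrogenase gene SDHB at 141 ± 34.7 against 354 ± 27.3 FPKM (adjusted p = 0.000856). The list also passed with autosomal genes only (adjusted p = 0.02). All 8 mitochondrially encoded genes were listed at 0 in every library, so that part of the pathway gave no measurement.

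Transcripts stored in the oocyte moved in both directions. Of 16 tested members of the oocyte list 6 rose and 2 fell in androgenetic embryos, or 8 rose and 2 fell adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0988). DPPA3, a maternal factor that protects methylation after fertilization, stood at 16298 ± 1921 against 5730 ± 830 FPKM (log2 difference 1.51 ± 0.163; adjusted p = 1.77e-05), and the mRNA decay regulator BTG4 at 236 ± 148 against 32.3 ± 18.2 FPKM. NLRP7, which maternal imprinting requires in humans, stood at 10.00 ± 6.12 against 127 ± 29.9 FPKM (adjusted p = 3.74e-05). Of 12 tested genes of DNA methylation 3 rose and 2 fell. DNMT1, the maintenance methyltransferase, stood at 21.7 ± 2.67 against 4.78 ± 2.19 FPKM (adjusted p = 0.001), and ZFP57, a protector of imprints, was listed at 0 in all androgenetic libraries and averaged 8.20 ± 5.46 FPKM in parthenogenetic embryos. The repair glycosylase gene MBD4 fell (6.49 ± 2.23 against 26.6 ± 14.2 FPKM). The oocyte list passed camera without androgenetic embryo 1 (adjusted p = 0.0413) and without parthenogenetic embryo 2 (adjusted p = 0.0492).

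The p53 target genes MDM2 (206 ± 43.4 against 51.7 ± 24.9 FPKM), TIGAR (1359 ± 119 against 515 ± 48.5 FPKM) and GADD45A (44.0 ± 14.5 against 6.44 ± 2.78 FPKM) rose and BAX fell among 15 tested members of the damage list, in which 3 rose and 2 fell (camera adjusted p = 0.164). The cell cycle list had 6 rises and 8 falls among 33 tested genes, with TPX2 and CCNE2 higher and the replication helicase genes MCM3 and MCM7 lower. In the pluripotency list 5 rose and 3 fell of 14, among the latter ESRRB (0.126 ± 0.109 against 3.37 ± 1.37 FPKM). In the polycomb list 4 rose and 5 fell of 19. PCGF5 rose (11.6 ± 5.56 against 1.74 ± 0.142 FPKM), and MTF2 (20.3 ± 6.14 against 55.8 ± 8.50 FPKM) and the X-linked genes KDM6A (0.0495 ± 0.0990 against 4.33 ± 1.14 FPKM) and RBBP7 (30.9 ± 11.7 against 268 ± 165 FPKM) fell. Of 9 tested genes of X inactivation 1 rose and 1 fell, the latter being RLIM, itself X-linked (0.0246 ± 0.0492 against 8.89 ± 3.23 FPKM).

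Trophectoderm genes had 1 rise and 3 falls of 10 tested, with DAB2 higher (107 ± 30.8 against 18.7 ± 6.43 FPKM), EPCAM lower (43.4 ± 19.6 against 217 ± 97.2 FPKM) and the tight junction gene CLDN4 listed at 0 in all androgenetic libraries. In lists with under 5 tested members, the endoderm gene APOA1 (0.214 ± 0.427 against 13.7 ± 3.38 FPKM), MARCKS (0.10 ± 0.0849 against 5.01 ± 0.693 FPKM) and the immune adaptor gene TYROBP (0.141 ± 0.189 against 8.82 ± 3.13 FPKM) were lower. Candidates for placenta-specific imprinting had 3 rises and 1 fall of 8, with LIN28B, DNMT1 and SIAH1 (991 ± 431 against 146 ± 138 FPKM) higher. Of 5 genes with imprinting not based on DNA methylation in mouse, GRAMD1B (11.6 ± 8.64 against 0.0871 ± 0.0874 FPKM) and GAB1 (6.40 ± 2.78 against 1.95 ± 1.72 FPKM) rose. GAB1 was no longer called without androgenetic embryo 2 or 3 or parthenogenetic embryo 3 or 4 (adjusted p = 0.0874, 0.0774, 0.103 and 0.0788; up to 0.108 over all alternatives). Among housekeeping genes 7 fell of 16, including X-linked PGK1 and HPRT1 and the actin gene ACTB (95.2 ± 32.8 against 256 ± 90.5 FPKM), and this list passed camera without androgenetic embryo 3 (adjusted p = 0.0344). In the hypoxia list 1 rose and 4 fell of 14, with BNIP3 at 287 ± 182 against 867 ± 253 FPKM, and in the glycolysis list 2 fell of 9, PGK1 and ENO1 (337 ± 117 against 797 ± 306 FPKM). ENO1 was no longer called in 2 of 17 alternatives (adjusted p up to 0.058), and median-ratio scaling called 1 glycolysis gene higher and 1 lower. Ribosomal protein genes were mostly not called, with 4 rises and 1 fall among 31, among them RPS6 (1074 ± 118 against 606 ± 122 FPKM) and RPL10A (492 ± 67.0 against 1270 ± 397 FPKM). Median-ratio scaling called 10 of them higher and 1 lower, and the list passed camera without androgenetic embryo 1 (adjusted p = 0.038). Genes at imprinting control regions had 7 rises and 3 falls of 15, germline genes silenced by methylation 2 and 1 of 14, cytotrophoblast genes 1 and 3 of 7, nutrient transporters 1 and 1 of 7, and placental hormones 2 falls of 6. Adjusted over the list alone, the damage list had 4 rises and 2 falls, the cell cycle list 6 and 9, the placenta-specific imprinted list 3 and 2, the ribosomal list 2 and 1 and the housekeeping list 8 falls, and the other lists of this and the preceding paragraph had the same counts. After median-ratio scaling the balance turned in the cell cycle list, with 7 rises and 5 falls, and in the polycomb list, with 5 and 3. Quantile normalization also turned the hypoxia list, with 3 rises and 2 falls against 3 and 4 after median-ratio scaling, and gave 2 rises and 1 fall in the X inactivation list, 1 of each in the cytotrophoblast list and no call among placental hormones.

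Of the 23 lists with at least 5 tested members, camera called the genome activation and oxidative phosphorylation lists only, and the adjusted p of the others ran from 0.0899 to 0.974. With an estimated correlation limma's camera called 0 lists, while 2 had an unadjusted p under 0.05 and fry called 14. Camera compares a list with all other genes, whose median lay below 0, and in 5 lists the direction it gave had another sign than the list's median or mean.

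Methylation in 16-cell embryos was higher in parthenogenetic than in androgenetic embryos, with autosomal means of 47.3% and 31.9%. Of 897904 tiles of 1 kb with at least 5 CpGs measured in both libraries, 178651 (19.9%) were at least 50 percentage points higher in parthenogenetic embryos and 28324 (3.154%) at least 50 points higher in androgenetic embryos. The tiles higher in parthenogenetic embryos had medians of 27% in androgenetic and 87.5% in parthenogenetic embryos. Those higher in androgenetic embryos had medians of 62.9% and 3.333%. With 1 library per group there is no replicate test. Levels from alternate CpGs of each tile within 1 library, odd against even, were compared in tiles with at least 5 CpGs in each set. They differed by 50 points in 18 of 470198 tiles in androgenetic and 42 of 551487 in parthenogenetic embryos. This covers the noise within a library only, and leaves out called tiles with fewer CpGs. Noise that neighbouring CpGs on the same reads share is not covered. Coordinates of the cynomolgus regions follow the deposited files, whose genome build is not given in the sources used here, and no gene annotation of that build was used.

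The region with the most CpGs in tiles higher in parthenogenetic embryos lay at the start of chromosome 8, from 1 to 74000, at 4.0% in androgenetic and 81.9% in parthenogenetic embryos. Next, with 1189 CpGs each, were chromosome 10 from 3745001 to 3797000, at 26.2% and 85.6% and at 84.3 to 87.8% in the adult tissues and placenta, and chromosome 14 from 10416001 to 10477000, at 25.6% and 84.1%. In the other direction, chromosome 9 from 132636001 to 132659000 stood at 81.5% in androgenetic and 10.5% in parthenogenetic embryos, and chromosome 14 from 1965001 to 1979000 at 77.5% and 1.0%. These 2 regions were at 49.3% and 45.2% in placenta and higher in the 6 adult tissues, at 73.5 to 80.2% and 57.8 to 69.7%.

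**Figure D3:**
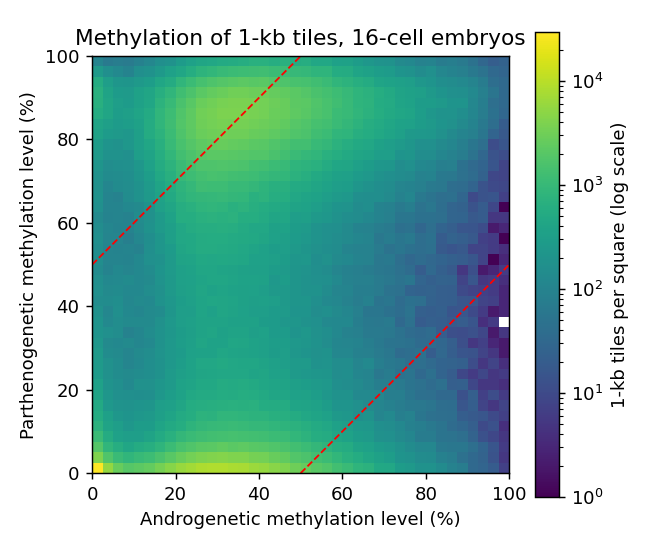
Methylation of 897904 tiles of 1 kb in androgenetic (horizontal axis) and parthenogenetic (vertical axis) 16-cell embryos, in percent, with the number of tiles per square as a log colour scale. Dashed lines mark a difference of 50 percentage points; 178651 tiles lie on or above the upper line and 28324 on or below the lower line.

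A parental difference that is kept after fertilization would leave tissues of 2 parents near 50% methylation. The clearest region of this kind lay on chromosome 10 from 90741001 to 90748000. Over 358 CpGs in 7 tiles it stood at 2.0% in androgenetic and 91.6% in parthenogenetic embryos, at 44.2 to 47.9% in the 6 adult tissues and at 50.0% in placenta. Chromosome 19 from 57553001 to 57559000 stood at 1.3% and 90.5%, with 46.8 to 52.7% in the tissues. Chromosome 3 from 163251001 to 163254000 stood at 1.3% and 92.0% with 41.2 to 56.4% in the tissues, and chromosome 16 from 17518001 to 17520000 at 1.0% and 90.6% with 51.8 to 57.2%. On chromosome 1 from 226277001 to 226280000 the tissues stood at 40.6 to 64.8% and the placenta at 10.9%. With the opposite parental direction, chromosome 14 from 1971001 to 1973000 stood at 86.3% in androgenetic and 0.8% in parthenogenetic embryos, at 48.8 to 61.2% in the tissues and at 50.6% in placenta.

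Such regions were a small part of the parental differences. Of 165486 tiles higher in parthenogenetic embryos and measured in the tissues, 3773 (2.28%) were at 35 to 65% in at least 5 of the 6 tissues, below the 3.038% among all tiles of the same CpG number. Of 25381 tiles higher in androgenetic embryos 503 (1.982%) were, against 2.854%. In tiles with at least 40 CpGs the share was above the background, at 4.208% (168 of 3992) against 2.55% for tiles higher in parthenogenetic embryos, and at 4 of 76 (5.263%) for those higher in androgenetic embryos. With a parental difference of at least 70 points the ratio to the matched share rose from 0.751 to 1.13 for tiles higher in parthenogenetic embryos.

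Adult tissues differed most from the placenta. Autosomal methylation averaged 67.1% in small intestine to 74.9% in cortex and 50.6% in placenta, and the correlation across tiles was 0.705 to 0.831 between the adult tissues and 0.434 to 0.615 between placenta and the 6 tissues. Of 1011827 tiles measured in all 7 libraries, 67405 (6.662%) were at least 40 points lower in placenta than in every other library. Among the adult tissues, cerebellum had 2098 such tiles, liver 401, small intestine 226, kidney 182, heart 70 and cortex 32. The placenta library was made by another protocol than the 6 tissues, so that part of this difference cannot be told apart from the protocol. Without the placenta the counts of low tiles rose to 3957 in cerebellum, 1107 in liver and 118 in cortex.

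In placenta, chromosome 20 from 1208001 to 1218000 stood at 29.7% against 78.0 to 87.1% in the tissues, and chromosome 14 from 195001 to 202000 at 16.6%. In cerebellum, chromosome 1 from 226146001 to 226155000 stood at 17.6% against 68.7 to 78.1% elsewhere. Single-tissue low regions were also found in heart (chromosome 6 from 131816001 to 131817000, at 20.2%), liver (chromosome 12 from 125720001 to 125722000, at 38.6%), kidney (chromosome 17 from 57817001 to 57819000, at 28.8%) and small intestine (chromosome 19 from 4073001 to 4074000, at 35.3%).

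The SCNT placenta of rhesus macaque was more methylated than the wild-type placenta, with autosomal means of 62.4% and 51.9%, and donor fibroblasts stood at 64.4% and 66.7%. Of 2031446 tiles, 155421 (7.651%) were at least 30 points higher and 3240 (0.1595%) at least 30 points lower in SCNT, and the median tile was 10.8 points higher. The same rule between the fibroblast libraries gave 12419 tiles higher and 3689 lower of 2026895. Tiles higher in SCNT had medians of 33.0% in wild type, 69.0% in SCNT and 73.9% in fibroblasts, against 52.4%, 66.8% and 72.75% over all tiles. Tiles lower in SCNT had medians of 67.9%, 32.3% and 44.3%. After each library was centred on its median tile, 9761 tiles were higher and 32538 lower in SCNT, so the share of differing tiles that were higher went from 97.96% to 23.08%. Centring takes 1 amount from every tile of a library. Yet tiles at 85 to 100% in wild type had medians of 89.3% in wild type and 90.8% in SCNT. Dense tiles at most 5% in wild type and fibroblasts averaged 1.211% and 1.586%. Centring moves such tiles toward lower in SCNT, so these counts cannot tell whether the gain is a shift between libraries. With 1 placenta per group the difference has no replicate check.

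With tiles grouped by wild-type level, the median rose most in tiles at 15 to 35%, from 27% in wild type to 46.3% in SCNT. Tiles at 0 to 15% went from a median of 10% to 20.5%, and tiles at 85 to 100% from 89.3% to 90.8%. Tiles of the highest group have little room to rise, because a level cannot exceed 100%. Noise in the wild-type library also enters the grouping and raises the gain of low groups. These medians therefore cannot show whether the gain depended on the wild-type level. In rheMac8 coordinates, chromosome 20 from 73233001 to 73252000 stood at 33.1% in wild type, 71.7% in SCNT and 84.8% and 82.9% in the fibroblasts. Chromosome 12 from 10103001 to 10123000 stood at 40.3% in wild type and 85.7% in SCNT. Among regions lower in SCNT, chromosome 16 from 70343001 to 70346000 stood at 75.9% in wild type, 21% in SCNT and 21.2% and 17.2% in the fibroblasts.

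Some CpG-dense regions with intermediate methylation in wild-type placenta were low in SCNT. Intermediate levels were common, with 29755 dense tiles intermediate in both placentas, so the level alone does not mark an imprinted region. Chromosome 17 from 93637001 to 93640000 stood at 42.4% in wild type, 7.5% in SCNT and 16.9% and 20.8% in donor fibroblasts, over 330 CpGs. Chromosome 14 from 122151001 to 122155000 stood at 37.1%, 3.8%, 8.8% and 12.6%, and chromosome 5 from 9842001 to 9845000 at 38.9%, 6.0%, 12.5% and 18.2%. In all, 362 dense tiles in 313 regions were at 35 to 65% in wild type and at most 15% in SCNT, with fibroblasts at a median of 10.7%. The mirror class, intermediate in SCNT and at most 15% in wild type, held 492 tiles with fibroblasts at a median of 64.1%. Among dense tiles intermediate in wild type, 17.7% of the 1353 with fibroblasts at 0 to 15% had fallen to at most 15% in SCNT, against 0.0927% of the 22645 with fibroblasts at 35 to 65%. Most dense tiles intermediate in both fibroblast libraries were not lost. Of 29793 such tiles, 54.1% were intermediate in wild type and 63.1% in SCNT, with medians of 40.6% and 57.8%. Above 65% were 11.1% in wild type and 27.6% in SCNT, and at most 15% were 2.18% and 0.812%. The number lost was sensitive to the limits, and at most 25% in place of 15% gave 1083 tiles lost in SCNT against 4832 in wild type.

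**Figure D4:**
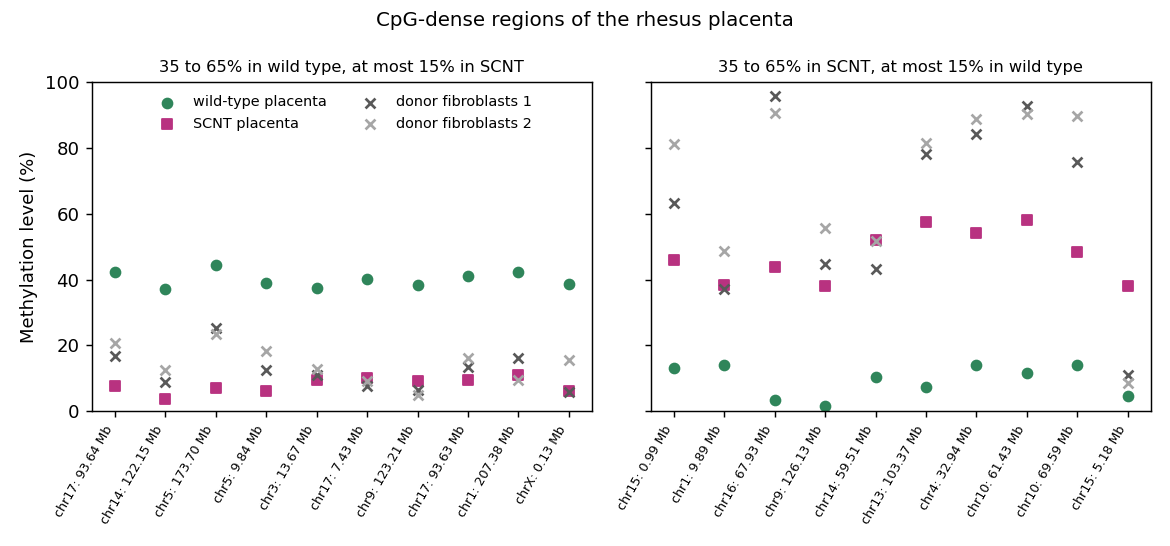
Methylation, in percent, of the 10 regions with the most CpGs that were intermediate in wild type and low in SCNT (left) and the 10 of the mirror class (right), by chromosome and start in megabases of rheMac8; each symbol is 1 library. On the left the wild-type placenta lies between 37.1% and 44.5% and the SCNT placenta between 3.8% and 10.9%.

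In RNA, the SCNT placenta had more of several groups of genes and less of extravillous trophoblast genes, the invasive cells of the placenta. Of 7749 genes with at least 5 FPKM in the higher library, 1455 were higher and 525 lower in SCNT by at least 1 on the log2(FPKM + 1) scale, with 1 library per group and no test. The median gene was 0.388 higher in SCNT, and after median-ratio scaling 672 genes were higher and 890 lower, or 43.0% higher against 73.5%. Extravillous trophoblast genes had 1 higher and 7 lower among 14 measured (median -1.32, below all 10000 random lists of the same expression), with AOC1 at 1337 FPKM in wild type and 61.2 FPKM in SCNT, PLAC8 at 1634 and 148 FPKM, fibronectin FN1 at 1819 and 294 FPKM and the maternally expressed regulator ASCL2 at 65.7 and 9.12 FPKM. Syncytiotrophoblast genes, of the fused outer layer, had 9 higher and 2 lower among 17 (median 1.86, percentile 100), including the fusion gene ERVFRD-1 at 1.96 and 27.4 FPKM, HSD11B2 at 2.18 and 35.5 FPKM and the sulfate transporter SLC13A4 at 1.54 and 36.9 FPKM. Median-ratio scaling gave 1 higher and 8 lower for the former list and 9 higher and 3 lower for the latter. Cytotrophoblast genes had 5 higher and 1 lower of 13 (median 0.688, percentile 98.55), or 3 and 2 after median-ratio scaling. Primitive endoderm genes had 6 higher and 2 lower of 12 (median 0.873, percentile 98.91), or 4 and 4 after median-ratio scaling.

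Immune and blood genes were also higher in the SCNT library. Lymphocyte and natural killer genes were higher in 7 of 8 measured (median 3.54), with GNLY at 0.494 and 39.9 FPKM and GZMB at 1.63 and 41.7 FPKM. Macrophage genes were higher in 13 of 15 (median 1.84), with LYZ at 26.99 and 402 FPKM and CD14 at 9.67 and 63.0 FPKM. Interferon-response genes were higher in 15 of 16 (median 1.97), or in 8 after median-ratio scaling, with CXCL10 at 1.11 and 51.0 FPKM and MX1 at 1.80 and 23.4 FPKM. Cell cycle genes were higher in 15 of 18 (median 1.75), or in 9 after median-ratio scaling, with MCM5 at 0.876 and 12.5 FPKM. Erythroid genes were higher in 4 of 5, with the fetal globin gene HBG2, which has a close copy, at 1631 and 10488 FPKM. The neutrophil and inflammation list went the other way, with 1 higher and 6 lower of 12 (median -1.02), including S100A9 at 76.6 and 12.0 FPKM and IL6 at 19.5 and 1.96 FPKM. Endothelial genes had a median of -0.307 (percentile 0.11), below the central 95% of their random lists, with 1 higher and 2 lower of 14, or 1 and 5 after median-ratio scaling, and VWF at 31.6 and 12.0 FPKM. Placental hormones had 7 higher and 6 lower of 20 and a median of -0.309 (percentile 1.36), below the central 95% of their random lists, among them KISS1 at 2.01 and 39.3 FPKM and INHA at 263 and 27.1 FPKM. Nutrient transporters were higher in 8 and lower in 2 of 21 (median 0.942, percentile 100), but higher in 3 and lower in 4 after median-ratio scaling, with a median of 0.519. Stromal and matrix genes stayed within the central 95% of their random lists (4 higher and 5 lower of 22), with DPT, which encodes a matrix protein, at 423 and 9.30 FPKM as 1 of the largest decreases outside the list.

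Imprinted genes differed in both directions between the placentas. Paternally expressed genes had 5 higher and 3 lower among 17 measured (median 0.711, percentile 98.05), or 5 and 4 after median-ratio scaling, with a median of 0.349. DLK1 stood at 212 FPKM in wild type and 1549 FPKM in SCNT, MEST at 459 and 1604 FPKM, PEG10 at 12.0 and 47.6 FPKM, PLAGL1 at 6.998 and 22.2 FPKM and NNAT at 2.63 and 12.2 FPKM, while ZNF331, DIRAS3 and NDN were lower. Maternally expressed genes had 3 higher and 4 lower among 18 (median 0.175, percentile 31.15), or 2 and 4 after median-ratio scaling, with a median of -0.231. Among the lower ones were CPA4 at 100.03 and 4.63 FPKM, TFPI2 at 126 and 8.93 FPKM and CDKN1C, a growth inhibitor, at 1188 and 375 FPKM. The higher ones were NTM at 0.516 and 8.11 FPKM, NLRP2 at 5.18 and 25.2 FPKM and GRB10 at 12.1 and 26.4 FPKM, the last of which was not called after median-ratio scaling. Placenta-specific imprinted genes had 5 higher and 3 lower among 15, or 4 and 4 after median-ratio scaling, within the central 95% of their random lists, with DNMT1 at 2.64 and 41.1 FPKM and GPR1 at 21.5 and 1.72 FPKM. The largest increases over all genes were in genes listed at 0 in wild type, among them GABARAPL2 at 13867 FPKM and SERPINE2 at 1064 FPKM in SCNT. RPL39 and RPLP1, ribosomal protein genes used by every cell, were listed at 0 in SCNT and at 570 and 479 FPKM in wild type, so a listed 0 can be a failed estimate in these files.

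**Figure D5:**
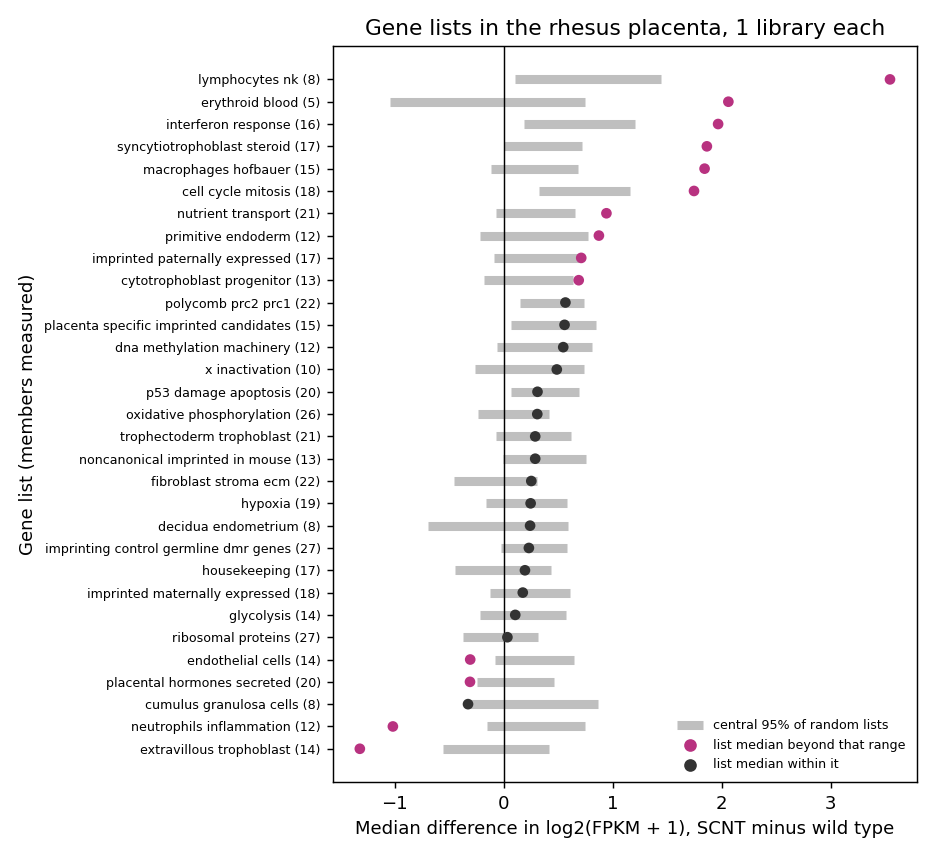
Median difference in log2(FPKM + 1) between the SCNT and wild-type placenta for each gene list with at least 5 measured members (points), with the central 95% of 10000 random lists matched on expression (grey bars). Extravillous trophoblast genes lie lowest at -1.32, and lymphocyte and natural killer genes highest at 3.54.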

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

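All tests of explanations in this part, including the counts over other splits of the libraries, were written down after the results were seen. The rule for a library apart from its group was set before. In 174 groups of 4 embryos, over 84 genes and 3 totals per library, 10 groups held a library whose gap to the nearest other exceeded Dixon's 95% critical share of the group's range on the log2 scale, where chance gives about 1 in 20. In 5 of these a single library had a low value while the other 3 were listed at 0, a gap of 1.0 of the range. These were C4H6orf163 in parthenogenetic embryo 3 (0.392 FPKM), KDM6A in androgenetic embryo 2 (0.198 FPKM), RLIM in androgenetic embryo 3 (0.0984 FPKM), NDN in androgenetic embryo 1 (0.374 FPKM) and APOA1 in androgenetic embryo 4 (0.855 FPKM). DUXA was lower in parthenogenetic embryo 2 (236 against 775 to 933 FPKM, gap 0.864), and IFITM1 in parthenogenetic embryo 4 (187 against 675 to 865 FPKM, gap 0.838). MCM3 was higher in androgenetic embryo 1 (3.89 against 2.21 to 2.36 FPKM, gap 0.89), MCM7 in parthenogenetic embryo 4 (36.9 against 21.2 to 22.8 FPKM, gap 0.876) and RPS6 in parthenogenetic embryo 1 (788 against 530 to 561 FPKM, gap 0.856).

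Mitochondrial CpGs, which no comparison of the report used, had a mean level of 33.9% in androgenetic and 36.2% in parthenogenetic embryos, against 2.43 to 5.42% in the cynomolgus tissues and placenta, and the bisulfite conversion of the mitochondrial genome in the embryo libraries was not checked.

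X-linked RNA was near 0 in all 4 androgenetic embryos. A lower yield or scaling of these libraries would have lowered matched autosomal genes alike, but the lowest of 1000 matched autosomal medians was -0.638 against -3.57 for X-linked genes. Loss of X-linked genes in mapping or annotation is argued against by the parthenogenetic libraries, the lowest of which had 16601 FPKM from X-linked genes. Open are embryos without an X chromosome, as from Y-bearing sperm, and a paternal X that is present but not transcribed. The androgenetic methylation library, a separate library, held 40% of the X-linked CpGs measured in cortex and 76.2% of the autosomal ones, and cannot tell which of these holds for the 4 RNA embryos. In RNA, the 1 tested gene of the Y-linked list was 1.24 higher on the log2 scale in androgenetic embryos. It passed only when adjusted over the list alone, and 1 gene cannot decide between these explanations.

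The 2317 genes called between the embryos exceeded all other splits of the 8 libraries. Of the 35 splits into 4 and 4, 1 gave as many, the real one, and the highest other split called 0 genes. Every other split mixes both kinds of embryo, so a difference between the kinds adds to the spread within its groups. These counts therefore cannot show how many genes chance alone would call. For lists, 14 of the 35 splits, the real one among them, called at least its 2 lists, and the highest other split called 6. Splits that hold the kinds in unequal numbers keep part of the difference between them, as did the split with 6. These counts therefore cannot show how many lists chance alone would call either.

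Genome activation genes were higher in androgenetic embryos, with 12 members called higher under the scaling that gave fewer, which argues against the scaling of the libraries as the cause. Slower development of androgenetic embryos, with activation transcripts not yet cleared, may account for it and would also leave oocyte transcripts higher. That list pointed higher without passing camera (adjusted p = 0.0988), with 6 of 16 tested members rising and 2, NLRP2 and NLRP7, falling. It passed camera without androgenetic embryo 1 or without parthenogenetic embryo 2 (adjusted p = 0.0413 and 0.0492). The delay is therefore neither supported nor excluded. A parental difference in the activation of these genes stays open as the difference the design names, and was not tested apart from the delay.

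The SCNT placenta had gained methylation over the genome and lost it at some dense tiles. Incomplete bisulfite conversion in SCNT would raise fully unmethylated tiles, but dense tiles at most 5% in wild type and fibroblasts rose by 0.375 points on average, against 10.8 points for the median tile. Donor-fibroblast-like cells at 1 share in every region stay open. The shares did differ between 808 tiles (r = 0.957 between odd and even CpGs of a tile). In 19.55% of these tiles SCNT lay above wild type, away from the fibroblasts. In 34 tiles it lay below both fibroblast libraries, where no share of the 2 sources would place it. Differences between the 2 animals, added to 1 share, could give the same. Another cell makeup of the placenta pieces stays open, since 8 of 10 cell type lists lay beyond the central 95% of random lists, with extravillous trophoblast at -1.32 and syncytiotrophoblast at 1.86, and 1 library per group cannot part makeup from cloning. Methylation kept from the donor nucleus is a further candidate explanation, and was not tested apart from these.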

How the results depend on the processing

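The autosomal fits and the runs on CpGs measured in both libraries were chosen after seeing the data, and the other alternatives before. Among 104 named embryo genes, 1724 results under alternatives included 1609 with the same call and 115 in which the call was lost, spread over 24 genes, and none changed direction. For 127 named placenta genes 554 of 635 kept the call. All 40 named regions of the parental and rhesus comparisons kept theirs on CpGs measured in both libraries. Coverage minimums of reads per CpG were not run, because the files give no coverage, so the effect of depth on the methylation levels is unknown. The cause of the changes listed here was not tested, except that stricter limits leave fewer tiles and genes to call.

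The embryo comparison called 2317 genes and between 1857 and 2284 with 1 library left out. The replicate numbers did not pair the libraries. Deviations of same-numbered libraries correlated at -0.00557, 0.126, 0.00719 and -0.0745, and 2 of the 8 libraries correlated best with their own number. With the number as a replicate block 2194 genes were called. Of the 104 genes named by the rule, the calls of ZNF597, GNLY and ITGA6 ended. Genes that the text names outside that rule were not followed. Quantile normalization gave 1103 higher and 1011 lower (52.2% higher), and median-ratio scaling 992 higher (45.8%). Autosomal genes alone gave 1930 calls. The number of lists called, 2, became 4 without the filter, 0 with an estimated correlation and 2 to 4 with 1 library left out. It was 4 without androgenetic embryo 1, when the oocyte and ribosomal protein lists passed as well (adjusted p = 0.0413 and 0.038).

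For the parental tiles (206975 called in all), tiles of 2 kb gave 95328 (85579 higher in parthenogenetic and 9749 in androgenetic embryos), at least 10 CpGs 100403 (91014 and 9389), a difference of 40 points 357776 (291886 and 65890) and of 70 points 29171 (25300 and 3871). At least 3 CpGs gave 46022 tiles higher in androgenetic embryos. Intermediate parental tiles numbered 10011 at 30 to 70%, 1250 at 40 to 60%, 1374 in all 6 tissues, 849 with a parental difference of 70 points and 2332 with at least 10 CpGs, against 4276. The ratio to the matched share for tiles higher in parthenogenetic embryos was 0.780 at 30 to 70%, 0.718 in all 6 tissues and reversed to 1.13 with 70 points, against 0.751. For tiles higher in androgenetic embryos it was 0.595 in all 6 tissues, against 0.695.

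Tissue-specific low tiles (70414) became 177435 at 30 points (cortex 279, cerebellum 5273, heart 378, liver 1464, kidney 772, small intestine 1021, placenta 168248), 31162 with at least 10 CpGs (cortex 13, heart 27, liver 165, kidney 76, small intestine 98, placenta 29348) and 6886 without placenta (cortex 118, cerebellum 3957, heart 284, liver 1107, kidney 614, small intestine 806).

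For the rhesus placentas 20 points gave 537154 tiles (520770 higher and 16384 lower in SCNT), 50 points 2955 (2881 and 74), at least 10 CpGs 71819 (70342 and 1477) and tiles of 2 kb 54898 (54349 and 549). Centring on the median tile gave 42299 (9761 and 32538) and brought the share that was higher down to 23.08%. It also moves tiles that stood alike in both placentas toward lower in SCNT. Dense tiles lost in 1 placenta numbered 1383 at 30 to 70% (619 lost in SCNT and 764 in wild type), 5915 with the low limit at 25% (1083 and 4832, ratio 0.224) and 3197 with at least 10 CpGs per kb (2738 lost in wild type, ratio 0.168), against 854 and a ratio of 0.736. In placenta RNA, at least 10 FPKM gave 953 genes higher, median-ratio scaling 672 higher and 890 lower (43.0% higher), and a log2 difference of 2 gave 521 (341 and 180).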

Other observations

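All tests of this part were chosen after the values were seen. Some dense tiles were low in every adult tissue and intermediate in the cynomolgus placenta alone. Chromosome 7 from 124785001 to 124791000 stood at 1.5% in androgenetic and 91.2% in parthenogenetic embryos, at 2.0 to 8.3% in the 6 adult tissues and at 45.1% in placenta. Chromosome 9 from 114295001 to 114297000 stood at 1.3% and 92.5%, at 1.1 to 1.7% in the tissues and at 51.5% in placenta, and chromosome 17 from 94642001 to 94645000 at 1.0% and 88.0%, 2.0 to 6.0% and 46.2%. A candidate explanation is that methylation of the maternal genome is kept in placenta and erased in the other tissues. Of 402 dense tiles at most 15% in all 6 tissues and at 35 to 65% in placenta, 209 (51.99%) were at least 50 points higher in parthenogenetic embryos, and 0 were higher in androgenetic embryos. Among the 19693 tiles that were also at most 15% in placenta, 276 (1.402%) were higher in parthenogenetic embryos and 1 in androgenetic embryos. These tiles had medians of 0.861% in parthenogenetic and 0.976% in androgenetic embryos. Over all 129146 dense tiles measured in both embryo libraries, 22.43% were at least 50 points higher in parthenogenetic embryos. Of the tiles low in all 6 tissues, the share was 18.86% of 1596 above 15 and below 35% in placenta. It was 42.86% (9) of 21 tiles above 65%, a level that 1 kept allele would not give, so it was not particular to intermediate tiles. The test could have come out otherwise, but with 1 library per tissue and another protocol for placenta it remains a hypothesis.

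Among the 10 largest parental regions that were intermediate in tissues, 5 resembled each other closely. Chromosome 13 from 12521001 to 12533000, chromosome 8 from 8534001 to 8549000, chromosome 11 from 11460001 to 11476000, chromosome 15 from 5465001 to 5477000 and chromosome 9 from 816001 to 825000 each had levels within 2.7 to 4.7 points of another of them in every library. They held 15.3 to 24.6 CpGs per tile, against 41.3 to 69.0 in the other 5 regions. Without a genome of this build it was not tested whether they share sequence.

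Mean methylation of the parthenogenetic library differed between chromosomes, from 41.4% on chromosome 1 to 58.4% on chromosome 17 and 57.0% on chromosome 18. Other libraries differed between chromosomes too. The androgenetic library ran from 26.5% on chromosome 19 to 34.6% on chromosome 18, and cortex from 64.3% on X to 77.2% on chromosome 18.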
